A study of Drosophila melanogaster with 4 samples.

How the data were processed

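Total RNA of wing imaginal discs, dissected by hand from wandering larvae, had been sequenced in 4 libraries, 2 from wild-type larvae (strain yw) and 2 from larvae carrying the warts allele wtsP2. Samples were grouped by their labels. The libraries were made with the SOLiD Total RNA-Seq kit, per the labels' protocols. HTSeq and DESeq are named in the submitters' processing notes without versions, as are the genome builds BDGP5 and dm3. The aligner, the strand setting and the tool behind the per-library files are not given in the sources used here.

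The authors deposited 1 file per library with the read count of each of 15222 gene features, its length and its position. The same files hold RPKM values, which the authors computed from those counts per the file headers. The sums of the counts lay above the library totals implied by the RPKM by 1.43%, 1.32%, 1.21% and 1.55%, and RPKM was used for nothing else. Features at the same position had equal counts in 170 cases, and 2869 tested genes (39.4%) share exon sequence with another gene in the annotation. How reads in shared sequence were assigned is not given. A table of the whole series holds the mean signal of each group, which the authors made with DESeq per the file headers as counts divided by size factors. Its fold column is the authors' ratio of the wtsP2 mean to the wild-type mean. Its log2 column held error codes and was left out. The nonzero means (8286 in wild type and 9875 in wtsP2) all split into 2 whole counts within a relative tolerance of 1e-09, with size factors of 0.942 and 0.376 in wild type and 1.84 and 1.76 in wtsP2. The recovered counts summed to other totals than the files and thus came from another counting of the same libraries.

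Library totals ran from 696952 to 3846682 counts. A floor of 3 counts corresponded to 1.46 and 3.94 CPM in wild type and to 0.860 and 0.837 CPM in wtsP2. Floors cover counting error only. Small nucleolar and nuclear RNA genes took 11.0%, 12.7%, 9.23% and 13.3% of the counts, transcripts of the mitochondrial genome 0.0648%, 0.0387%, 0.0382% and 0.0280%, and the 10 highest genes 7.65%, 10.1%, 6.99% and 6.57%.

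The groups, the test, the gene lists, the rule for named genes and a set of alternatives were fixed before the data were examined. Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were filtered with filterByExpr (7278 kept, 7944 not tested), scaled by TMM and compared with the robust quasi-likelihood F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. Adjusted p-values are edgeR's unless another tool is named. Errors are the log2 fold change over the square root of F. Of 43 gene lists, 37 had at least 5 tested members and were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. With an estimated correlation, camera takes its degrees of freedom from the 4 libraries rather than from the genes. It could then call few lists, so a loss there alone does not show whether the preset correlation made the call. Genes were named if they were wts or among the 4 members of a described list with the smallest adjusted p. Where none was called, the 2 members with the highest level could be named too. Any member of the Hippo or Yki target lists could be named, and only some were. The rule also named the 10 largest called changes in each direction, of which there were none. Symbols came from the reference annotation by identifier, which matched 14347 features, and coordinates are those of the count files. Genes at 0 in a whole group are given as counts or as a bound from 3 counts over the group.

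The procedure was tested on counts simulated from the real means, library sizes and dispersions, with 200 genes changed. The dispersions were the fit's trend with level, alike in both groups, although the real groups differed in spread. Changed genes were drawn from those above a set level. Of 66 to 67 genes per fold size, 0% were called at 2-fold and at 4-fold and 6.06% at 8-fold. At a dispersion of 0.1, the shares were 8.96%, 68.7% and 100%. Camera found the changed list of 12 genes, and called 4 of 100 random lists at an unadjusted threshold of 0.05. Alternatives were other scalings, no filter and a stricter one, a stricter threshold, glmTreat, the replicate number as a block, DESeq2 1.42.0, limma-voom and each library left out. Recovered counts, thinned libraries, protein-coding genes alone, a curve on gene length taken out of each library and camera with a library left out were added after seeing the data.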

Results

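Transcripts of the wing imaginal disc, the larval epithelium that forms the adult wing and notum, were counted in Drosophila melanogaster at the third larval instar. The wild-type group (strain yw) and the wtsP2 group each held 2 libraries of total RNA from hand-dissected discs. The wtsP2 larvae carried an allele of warts (wts), which encodes the Hippo pathway kinase that restrains the transcriptional coactivator Yorkie (Yki). Summed over 15222 gene features, the counts came to 2112468 and 696952 in the wild-type libraries and to 3520970 and 3846682 in the wtsP2 libraries. Counts above 0 were found for 7023 and 5031 features in wild type and for 7842 and 8625 in wtsP2. Across the 7278 tested genes, which are not independent replicates, log2 CPM (counts scaled to library size) correlated at Pearson r = 0.564 between the wild-type libraries and at 0.868 between the wtsP2 libraries. Correlations between the groups ran from 0.574 to 0.659. Many genes of moderate level were at 0 in single libraries. Among genes for which the other 3 libraries predicted 20 to 40 counts, 28.7% and 37.2% were at 0 in the first and second wild-type libraries. In the wtsP2 libraries these shares were 28.2% and 21.9%, where Poisson counting gives at most 1.88e-07 such genes in any library. The prediction pools both groups, so genes that differ between the groups add to these shares. The labels did not say that the libraries of a group came from separate cultures. P-values of single genes thus measure the spread between these libraries, which could be technical. Camera's p-values for lists at the preset correlation of 0.01 take their degrees of freedom from the genes. They do not measure the spread between libraries, however small they are.

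**Figure D1:**
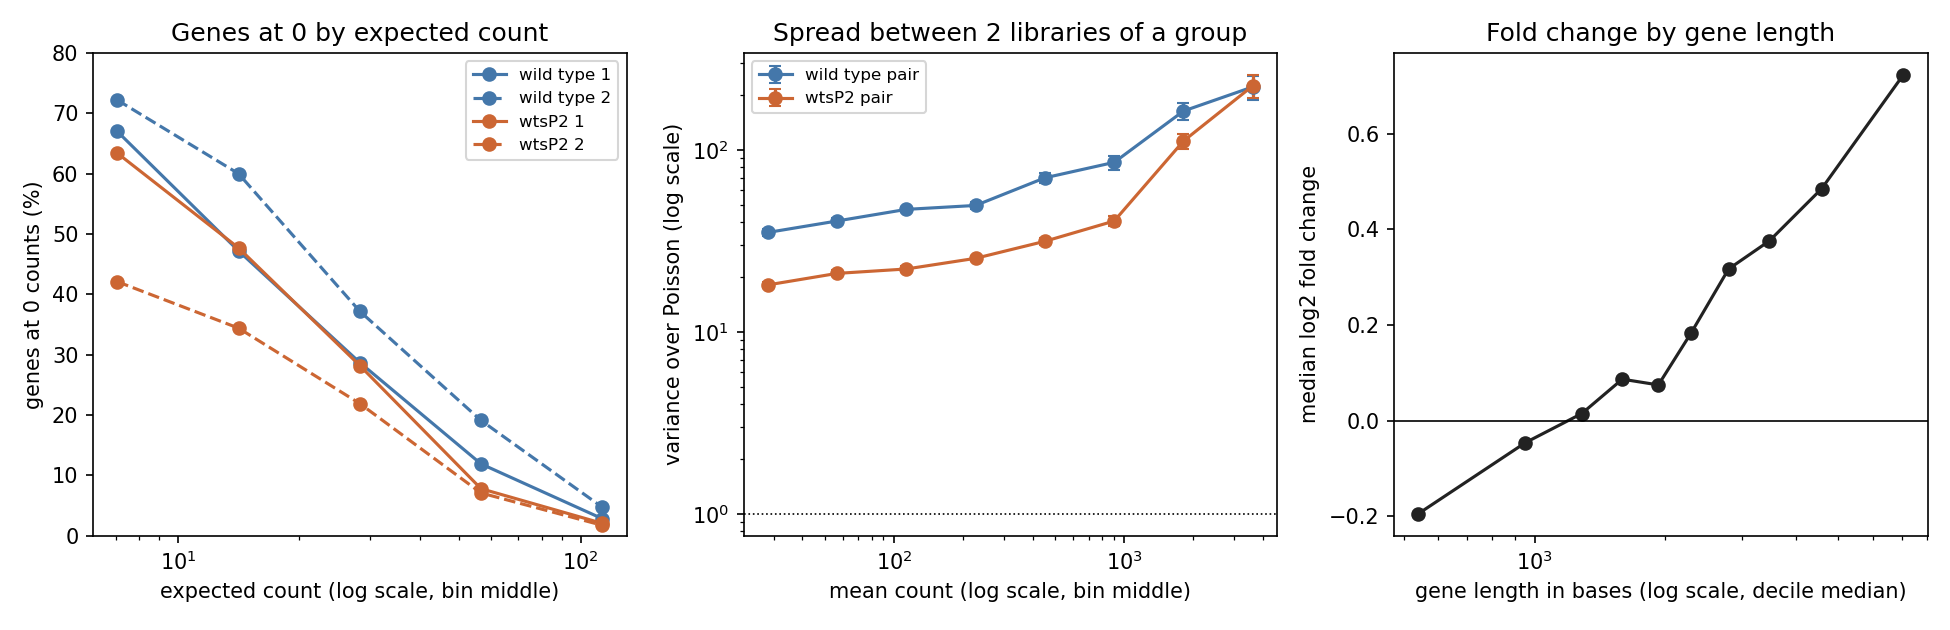
The left panel plots the share of genes at 0 counts (percent) against the count predicted from the other 3 libraries, per library; at 20 to 40 counts it lies between 21.9% and 37.2%. The middle panel plots the variance between the 2 libraries of a group over its Poisson value (mean ± SE over genes, both axes log) against mean count, and the right panel the median log2 fold change of wtsP2 over wild type in 10 classes of gene length, from -0.20 in the shortest to 0.72 in the longest.

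The comparison of wtsP2 with wild-type discs asked which transcripts depend on Warts. The wts gene itself (FBgn0011739; chromosome 3R, 26615379 to 26632341, minus strand, in the coordinates of the count files, build BDGP5) had 46 and 0 counts in wild type and 48 and 24 in wtsP2. Its log2 fold change was -0.15 ± 2.36 (SE, n = 2 per group; edgeR adjusted p = 0.999), too imprecise to check the genotype labels. As groups, larval fat body genes fell in wtsP2 (median log2 fold change -3.70 over 12 genes) and genes of the tracheal list rose (median 0.90 over 11 genes). Neither call held with an estimated correlation (adjusted p = 0.552 for both), and the tracheal call was lost without the first wild-type library (adjusted p = 0.136), where the list's median lay 0.72 above that of all genes, against 0.65 with all libraries. The expanded gene ex, a Yki target and a Hippo pathway regulator, was 6.0-fold higher in wtsP2, and the larval serum protein gene Lsp1gamma was 21.2-fold lower. No single gene passed the threshold in edgeR: 0 genes were higher and 0 lower at an adjusted p under 0.05. At an unadjusted p under 0.05, 721 genes were higher and 193 lower, 914 in all where chance gives 363.9, and the smallest adjusted p was 0.142. DESeq2 called 96 genes higher and 86 lower, and limma-voom 123 and 27. These counts are not like for like with edgeR's. DESeq2 was run without edgeR's filter on 9363 genes, of which 1997 got no adjusted p. The median log2 fold change of all genes was 0.775 by limma-voom, against 0.244 in edgeR. Of 60 genes named here besides wts, 35 passed in DESeq2 and 18 in limma-voom, Lsp1gamma among them (adjusted p = 2.40e-32 and 0.0192), while 45 and 44 passed without the first and second wild-type libraries and 10 without either wtsP2 library. Many of the 60 genes were named for small p-values in these same counts, so their shares are raised by the choice. The common biological coefficient of variation, pooled over both groups, was 92.8%. Without the first and second wild-type libraries, where only the wtsP2 pair gives a spread, it was 59.5% and 59.4%. Without either wtsP2 library, where only the wild-type pair gives one, it was 128%. Simulated counts took dispersions that followed level and were alike in both groups. They gave calls for 6.06% of 66 genes changed 8-fold and for 0 of 67 genes changed 4-fold. Unequal spreads were not simulated. Both wtsP2 libraries lay above both wild-type libraries for 2352 genes and below them for 1098, 47.4% of those tested against 33.3% by chance. That chance value takes the 4 libraries as alike. They were not, with correlations of 0.564 within wild type and 0.868 within wtsP2, so the excess is no measure of the genotype. The median log2 fold change of all tested genes was 0.24. The counts depended on single libraries, since leaving out the first wild-type library gave 2514 genes higher and 681 lower, around a median of all genes of 1.33, and leaving out the second gave 1002 and 463. In these fits the lone wild-type library is assumed to vary as the wtsP2 libraries do.

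Among genes of the Hippo pathway and its targets, ex and the upstream protocadherin gene ft (fat) had the smallest p-values. Both genes are long (6640 and 16178 bases, against a median of 2096 for all tested genes). Log2 fold changes rose with gene length, to a median of 0.72 in the longest of 10 classes. How far these rises follow that trend was not tested for single genes. The ex gene (chromosome 2L, 431253 to 448701) had 666 and 191 counts in wild type and 6301 and 5900 in wtsP2, a log2 fold change of 2.58 ± 0.36 (adjusted p = 0.340). At about the same fold, ex passed in DESeq2 (adjusted p = 4.54e-07) and limma-voom (0.0329), and without either wild-type library (0.000253 and 0.000256), but not without either wtsP2 library (0.0858 and 0.0650). For ft (1585, 644, 9938 and 14632 counts) it was 2.10 ± 0.36, and for crb (crumbs), an apical polarity determinant, 2.49 ± 0.67. The casein kinase gene dco had a larger value with a wide error, 3.14 ± 1.70 (56, 0, 495 and 392 counts). These values rested on single libraries: crb was at 3.69 without the first wild-type library and at 1.90 without the second, and dco at 2.24 without the second, while without the first it had no wild-type counts. The BTB transcription factor gene chinmo was at 1.52 ± 0.38. The JAK/STAT ligand gene upd1 had no counts in wild type and 45 and 23 in wtsP2, so that no fold is given for it. Other targets lay nearer to 0. The growth regulator gene Myc was at 0.48 ± 0.35, the apoptosis inhibitor gene Diap1 at 0.27 ± 0.34 and the Golgi kinase gene fj (four-jointed) at 0.00 ± 0.52 (-0.44 without the first wild-type library and 0.67 without the second). The wing selector gene vg was at -0.96 ± 0.42, yki at -1.04 ± 0.78 and Tgi, which encodes a repressor partner of Scalloped, at -1.74 ± 0.48. Of 33 tested members of the Hippo pathway list, 0 passed over all genes and 2, ex and ft, were higher adjusted over the list alone. Of 16 tested members of the Yki target list, 0 passed over all genes and 1, ex, was higher adjusted over the list alone. Neither list passed camera, a test of a list against all other genes (Yki targets, median 0.55, adjusted p = 0.107; Hippo pathway, median 0.09, adjusted p = 0.964). The Yki target list passed as higher without the second wild-type library (adjusted p = 0.0178) and without the second wtsP2 library (0.0444). The exon of ex overlaps crq in the annotation, and crq had 104, 65, 120 and 143 counts.

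**Figure D2:**
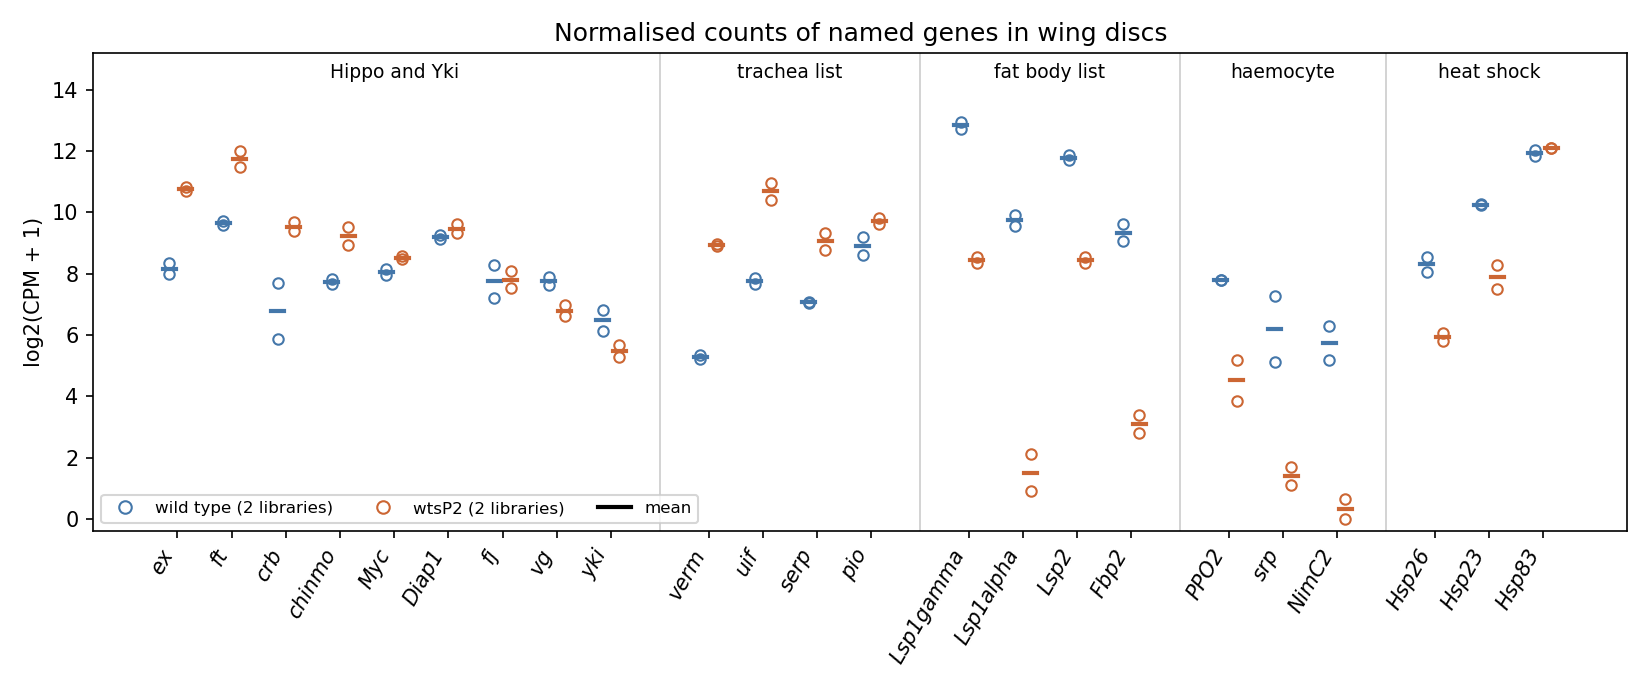
Each circle is the normalised count of a gene in 1 library, as log2(CPM + 1), and each bar the mean of a group's 2 libraries, for genes of the Hippo and Yki lists and of 4 other lists. The ex gene and the tracheal list genes verm, uif and serp lie higher in both wtsP2 libraries, and the fat body genes lie lower in both; log2 fold changes run from -8.64 for Lsp1alpha to 3.70 for verm.

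Genes of the larval fat body, the storage organ that lies against the discs in the body cavity, fell in wtsP2 as a list. Lsp1gamma had 16217 and 5194 counts in wild type against 1126 and 1332 in wtsP2 (log2 fold change -4.41 ± 0.37, adjusted p = 0.142). For Lsp2, which encodes another larval serum storage protein, the value was -3.34 ± 0.35. Lsp1alpha (1996, 576, 3 and 12 counts) was at -8.64 ± 0.78 (-7.95 to -9.87 without either wtsP2 library) and the fat body protein gene Fbp2 -6.41 ± 0.54. All 12 tested fat body genes had negative log2 fold changes, but some were near 0 or imprecise, such as the desaturase gene Desat1 at -0.64 ± 0.44 (chosen after its value was seen). None of the 12 passed over all genes and 7 were lower adjusted over the list alone. The list fell by camera (adjusted p = 1.14e-32), and the call was lost at adjusted p = 0.552 with an estimated correlation between the genes. Its median was -4.41 without the second wtsP2 library. Blood cell (haemocyte) genes fell as well (10 tested, median -0.72, camera adjusted p = 0.000153, and adjusted p = 0.552 with an estimated correlation). Their median lay 0.97 below that of all genes. Without the first wild-type library it lay 2.30 below, where the median of all genes was 1.33 and that of the list -0.97. The crystal cell gene PPO2, for a prophenoloxidase, was at -3.18 ± 0.68 (-4.01 and -2.63 without the first and second wtsP2 libraries) and was the 1 member lower adjusted over the list alone, against 0 over all genes. The GATA factor gene srp was at -5.75 ± 1.48 (-6.46 and -4.26 without the first and second wild-type libraries), and NimC2 had 73 and 59 counts in wild type against 0 and 2. The broad haemocyte genes Hml and Pxn, chosen after their values were seen, lay near 0 at -0.28 ± 0.63 and -0.31 ± 0.84. Salivary gland secretion genes had too few members for a list test with all libraries. With a library left out, the filter admits genes counted in 1 library, and 6 to 9 were tested. The list's median lay between -8.75 and -7.55 over the 4 fits. Members could enter through a library where they are high, and the fits share libraries. They are thus no repeated support. Sgs3 had 427 and 91 counts in wild type against 1 and 5, and Eig71Ee had no counts in wtsP2, at least 340-fold lower against a floor of 3 counts over the group. Of 4 tested salivary gland genes, 0 passed over all genes and 2 were lower adjusted over the list alone. The 3 tested gut and Malpighian tubule genes had a median of -7.04, or -6.11 with the gene at 0 in wtsP2 set to the bound from 3 counts over the group. The list's median was -3.51 and -7.95 without the first and second wtsP2 libraries, and -5.07 without the second wild-type library. Those 3 fits tested 7 to 8 members, admitted in the same way, and are likewise no repeated support. The gut and Malpighian tubule list had too few members without the first wild-type library. Muscle and myoblast genes (median -1.27, adjusted p = 0.136), eye disc genes (-1.42, 0.611), neuron and glia genes (-0.07, 0.964) and leg and haltere genes (-0.20, 0.964) did not pass, although the muscle list passed as lower without the second wtsP2 library (adjusted p = 0.0396) and with a curve on gene length taken out (0.0294). Germ line genes had 3 tested members with a median of 0.61. Paralogs such as the Lsp1 genes could share reads in the counting, so their single values are uncertain.

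Genes of the tracheal list rose in wtsP2 (camera adjusted p = 0.000153, and adjusted p = 0.552 with an estimated correlation). The chitin deacetylase genes verm (chromosome 3L; 74, 30, 1685 and 1781 counts) and serp were at log2 fold changes of 3.70 ± 0.40 and 2.03 ± 0.39. The transmembrane protein gene uif was at 2.95 ± 0.40, and the zona pellucida protein gene pio at 0.78 ± 0.37. The uif gene is long (11822 bases), where fold changes were higher in general, while verm and serp (2360 and 2531 bases) are not. Of the 11 tested members, 10 had positive values, 0 passed over all genes and 3 were higher adjusted over the list alone. Without the first wild-type library the call missed the threshold (adjusted p = 0.136), with the median 0.72 above that of all genes. The chitin list, which shares verm and serp, went both ways: the chitin synthase gene kkv was at 1.81 ± 0.40 and Idgf6, for an imaginal disc growth factor, at -2.25 ± 0.50. Of its 20 tested members, 0 passed over all genes, while 5 were higher and 2 lower adjusted over the list alone (median 1.22, camera adjusted p = 0.221). Cuticle genes spread widely around a median of 0.22, and the list did not pass (adjusted p = 0.305), except as lower without the first wild-type library (0.0374) or the first wtsP2 library (0.0135). Among them the larval cuticle protein gene Lcp4 had 472 and 225 counts in wild type and 3 and 2 in wtsP2, at -8.43 ± 0.68 (adjusted p = 0.142). It was the 1 cuticle gene lower adjusted over the list alone, against 0 over all genes. Of the junction and polarity genes, the septate junction gene cora was at 1.65 ± 0.33 and the E-cadherin gene shg at 1.18 ± 0.34. That list did not pass (24 tested, median 0.44, adjusted p = 0.240).

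**Figure D3:**
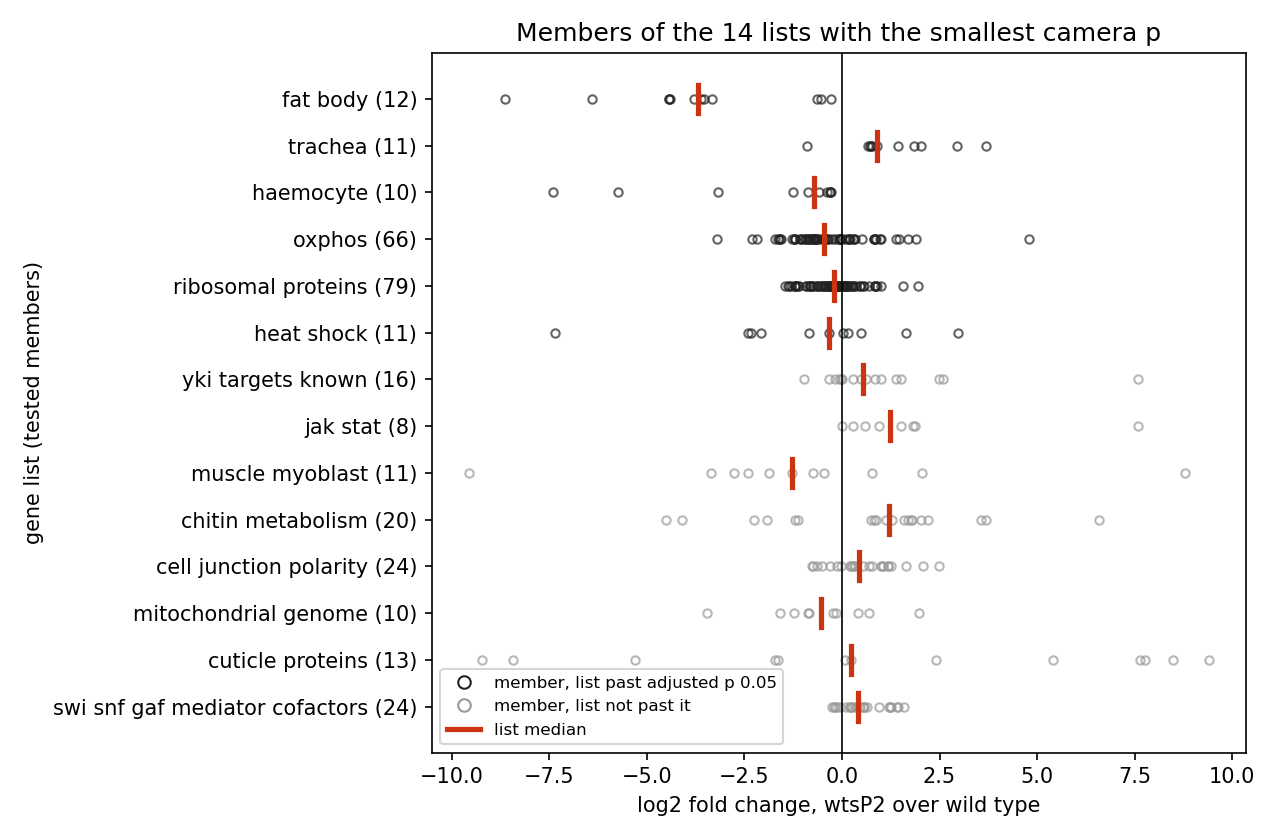
Each circle is the fitted log2 fold change (wtsP2 over wild type) of 1 tested member of a gene list, and each red bar the list's median, for the 14 lists with the smallest camera p. The 6 lists in black passed an adjusted p of 0.05 at the preset correlation, and 0 of them with an estimated correlation; the fat body list has a median of -3.70 and the tracheal list of 0.90, and the outermost circles are genes with no counts in 1 group, whose fitted values are not bounds.

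Genes for energy metabolism and translation shifted by small amounts. Oxidative phosphorylation genes fell (66 tested, median -0.45, camera adjusted p = 0.00149, and adjusted p = 0.937 with an estimated correlation). Examples were ox, for a subunit of respiratory complex III, at -3.20 ± 0.77, ND-PDSW of complex I at -1.62 ± 0.43 and ATPsynG of the ATP synthase at -1.64 ± 0.45. Of the 66 members 20 were positive, among them blw, for the abundant alpha subunit of the ATP synthase, at 0.85 ± 0.36 (chosen after its value was seen). Cytoplasmic ribosomal protein genes fell (79 tested, median -0.21, adjusted p = 0.00318, and adjusted p = 0.937 with an estimated correlation). They went both ways (29 positive), with RpL13A at -1.20 ± 0.36, RpL4 at 1.95 ± 0.41 and the abundant RpS7 and RpL3 at -0.29 ± 0.45 and -0.19 ± 0.36. In both lists 0 members passed over all genes and 0 adjusted over the list alone. Both lists consist of short genes (median lengths 780.5 and 782 bases against 2096 for all tested genes), and log2 fold changes rose with gene length across genes (Spearman rho = 0.176). With a length curve drawn without these genes taken out, the ribosomal call ended (adjusted p = 0.111; median -0.25 from that of all genes, against -0.46), and the oxidative phosphorylation call did not (0.0160). The curve took out only part of the trend (Spearman rho = 0.0751 after it). Medians were then 0.283 in the shortest and 0.468 in the longest class of genes. The call that remained thus does not exclude the trend. Both calls were lost without the first wild-type library, at adjusted p = 0.136 for oxidative phosphorylation and 0.989 for ribosomal proteins. In that fit the median of all genes was 1.33, and the lists lay further below it (-1.34 and -1.03) than with all libraries (-0.69 and -0.46). Their own medians rose as well (to -0.01 and 0.30), so the wider distance came from the other genes and not from a fall of the lists. Heat shock genes fell by camera (11 tested, median -0.32, adjusted p = 0.00786, and adjusted p = 0.932 with an estimated correlation). The small heat shock protein genes Hsp26 and Hsp23 were at -2.40 ± 0.43 and -2.33 ± 0.42, and the abundant chaperone gene Hsp83 at 0.16 ± 0.32. Of the 11 members 5 were positive, among them the small heat shock protein gene Hsp27 at 2.98 ± 1.46 (104, 1, 333 and 1185 counts; chosen after its value was seen), which was at 2.11 without the second wild-type library, passed without the first (adjusted p = 0.0238), where it had 1 wild-type count, and was at 3.67 and 1.87 without the first and second wtsP2 libraries. Of the 11, 0 passed over all genes and 3 were lower adjusted over the list alone. The heat shock call was lost when either wild-type library or the first wtsP2 library was left out (adjusted p = 0.549, 0.117 and 0.0911), with the list still below all genes by median (-1.27, -0.74 and -0.62, against -0.56 with all libraries). Mitochondrial ribosomal protein genes (median -0.21, adjusted p = 0.475), genes of the mitochondrial genome (-0.54, 0.291), mitochondrial fusion and fission genes (-0.04, 0.791) and ribosome biogenesis genes (0.12, 0.964) did not pass. The mitochondrial ribosomal list passed as lower without the second wild-type library (adjusted p = 0.0289).

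Among the lists for growth and patterning, 0 passed camera with all libraries. Without the second wild-type library the JAK/STAT list (adjusted p = 0.0223) and the list of chromatin and Mediator cofactors (0.00680) passed as higher. The S-phase gene Mcm2, of the replicative helicase, was at a log2 fold change of 1.74 ± 0.52 (2.33 without the first wild-type library) and the mitotic phosphatase gene stg (string) at 1.23 ± 0.38. Their lists, DNA replication with the G1/S genes (35 tested, median 0.34, adjusted p = 0.964) and mitosis (34 tested, 0.38, 0.964), lay close to the median of all genes. The receptor genes N (Notch) and tkv (the Dpp receptor thickveins) were at 2.14 ± 0.49 and 2.30 ± 0.48 (tkv at 2.89 without the first wild-type library), and boi, for a Hedgehog co-receptor, at 2.78 ± 0.43. The Notch list had a median of -0.06 (adjusted p = 0.964), Dpp signalling of 0.13 (0.674), Hedgehog signalling of 0.22 (0.964), Wingless signalling of 0.42 (0.729) and EGF receptor signalling of 0.55 (0.956). JAK/STAT genes, which include chinmo and upd1, were all positive (8 tested, median 1.24, adjusted p = 0.107). Wing patterning transcription factor genes had a median of 0.59 (27 tested, adjusted p = 0.781), with the wing field gene nub at 0.67 ± 0.35. The ecdysone-regulated genes went both ways: ImpE2 was at -2.67 ± 0.41 and Eip74EF, an early ecdysone response gene with 35, 0, 701 and 801 counts, at 4.50 ± 1.41 (17 tested, median 0.24, adjusted p = 0.629). Eip74EF was at 3.67 without the second wild-type library and had no wild-type counts without the first. The glycolytic aldolase gene Ald1 was at 2.79 ± 0.45 in a list with a median of 0.08 (adjusted p = 0.964). The Trl gene, which encodes the GAGA factor GAF, was at 1.22 ± 0.35, and its list of chromatin and Mediator cofactors had a median of 0.41 (24 tested, adjusted p = 0.317). Adjusted over the list alone, boi, Ald1 and ImpE2 were the 1 gene past 0.05 in each of their lists, against 0 over all genes, and 0 members passed either way in the Notch, Dpp, Wingless, EGF receptor, JAK/STAT, wing patterning, DNA replication, mitosis and cofactor lists. Medians of the remaining lists were 0.53 for JNK and injury genes (adjusted p = 0.699), 0.49 for insulin and TOR (0.964), 0.59 for basement membrane genes (0.867), 0.08 for apoptosis (0.867), -0.38 for proneural genes (0.729) and 0.55 for detoxification genes (0.964). In these 6 lists, and in the junction, ribosome biogenesis, muscle, eye, neuron and glia, leg and haltere, and mitochondrial lists, 0 members passed over all genes and 0 adjusted over the list alone. The cuticle, ecdysone, apoptosis and ribosome biogenesis lists had a positive median while camera gave them as lower, and the Notch list the reverse. For the mitochondrial ribosomal, proneural, neuron and glia, mitochondrial fusion, and leg and haltere lists the mean was positive and the median negative. Histone genes (2 tested, median 0.47) and genes of sex determination and dosage compensation (4 tested, median 0.69) were too few for a list test, as was the antimicrobial list with 1 tested member.

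The authors' deposited table gives a mean per group and a fold change per gene, with no p-value, so calls could not be compared with it. Of the genes tested here, 7225 were in that table, and 6386 had a finite fold change. The direction was the same for 90.2% of these, and for 96.6% of the 536 genes with an unadjusted p under 0.05. The log2 fold changes correlated at Pearson r = 0.859 across genes. Because both sets of values come from the same libraries, this is no independent evidence. In the authors' deposited table the fold change was 5.80 for ex, 3.85 for ft, 4.96 for verm and 0.0422 for Lsp1gamma. For verm the counts of the files gave a larger change, a log2 fold change of 3.70 against 2.31 from the ratio in the authors' deposited table. Some genes differed between the sources: Trl, whose exons overlap Tsen34 and CG42507, had means of 0 and 15.7 in the authors' deposited table, and 396, 135, 1532 and 1511 counts in the files. The nahoda gene, chosen here after its values were seen, had 0, 1, 1221 and 1535 counts in the files and means of 94.5 and 951 in the authors' deposited table. Other genes with small p-values, also chosen after their values were seen, were the cytoskeletal genes cher (filamin) at a log2 fold change of 2.56 ± 0.37 and shot (spectraplakin) at 2.35 ± 0.36, and regucalcin at -3.61 ± 0.38. Dscam4, of the same kind, had no counts in wild type and 505 and 353 in wtsP2, at least 114-fold higher against a floor of 3 counts over the group, a bound that covers counting error only. The cher and shot genes are long (9140 and 30371 bases), and log2 fold changes rose with gene length.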

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

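The length curve, the recovered and thinned counts, the protein-coding subset and the list tests with a library left out were chosen only after the results were seen. Against 0 genes in edgeR (914 at an unadjusted p under 0.05), there were 21 higher and 16 lower with no filter, 69 and 38 with the replicate block, 96 and 86 by DESeq2, and 123 and 27 by limma-voom. The median log2 fold change of all genes was 0.759 with the block and 0.775 by limma-voom, against 0.244 in the main fit. Their excess of higher genes lies on top of that shift. The other scalings, the stricter filter, threshold and glmTreat, the recovered and thinned counts, the protein-coding subset and the length curve gave 0 in both directions. The replicate numbers share only a number (correlation of deviations 0.00801), so the block is not a paired design. Leaving out 1 library gave 3 to 2514 genes higher and 14 to 681 lower; the lone library is then assumed to vary as the other group does. The wts value of -0.15 became 2.51 by limma-voom and 1.74 with the block, and ran from -1.09 to 7.75 with a library left out, above 0 without the first wild-type library, which leaves no wild-type counts, or the second wtsP2 library. Of 719 alternative values for the 60 named genes other than wts, 211 passed the threshold. Apart from fj, which at 0.00 has no sign to keep and ran from -0.44 to 0.67, 6 values of 4 genes changed sign. With a library left out, RpS7 ran from -0.69 to 0.35 and RpL3 from -0.37 to 0.07, both above 0 without the first wild-type library, where the median of all genes was 1.33. Hml ran from -0.76 to 0.46 (0.07 by limma-voom) and Pxn from -0.93 to 0.16. Of the 6 lists past camera, 0 passed with an estimated correlation (adjusted p 0.552 for fat body, haemocyte and trachea, 0.937 for oxidative phosphorylation and ribosomal proteins, 0.932 for heat shock) and 1 by fry. The estimates lay below the preset 0.01 for trachea (-0.0507) and haemocyte (-0.0717), and ran from 0.111 to 0.407 for the others. Ribosomal proteins were at 0.407 and oxidative phosphorylation genes at 0.135. Where the estimate exceeds the preset, the preset makes camera's p-values smaller, so these calls may rest on it. The fry test, of a list against no change rather than against other genes, gave adjusted p = 0.0247 for trachea, the 1 list past it, 0.0731 for fat body and haemocyte, 0.592 for oxidative phosphorylation, 0.812 for ribosomal proteins and 0.291 for heat shock. With a length curve drawn on all genes, ribosomal proteins reached 0.44, with a median of 0.05. Leaving out 1 library gave 4 to 11 lists, with adjusted p from 1.93e-05 to 0.989 for ribosomal proteins (median -0.50 to 0.30), 0.00128 to 0.136 for oxidative phosphorylation, 0.0155 to 0.549 for heat shock (median -0.46 to 0.06) and 0.00271 to 0.136 for trachea. Relative to the median of all genes, ribosomal proteins lay lower in each of these fits (-1.03 to -0.40), as did oxidative phosphorylation (-1.34 to -0.51) and heat shock genes (-1.27 to -0.42), and tracheal genes lay higher (0.70 to 0.91). For the lower lists the widest distance came without the first wild-type library. There the median of all genes was 1.33, so that distance is no firmer evidence. Lists gained with a library left out included the Yki targets, JAK/STAT, cofactor, mitochondrial ribosomal, cuticle and muscle lists. Fat body (1.91e-18 to 6.34e-06, median -4.41 to -3.39) and haemocyte genes (1.69e-05 to 0.00570, median -0.97 to -0.61, or -2.30 to -0.90 relative to all genes) passed in each case. The salivary gland list, too small for a test with all libraries, had a median from -8.75 to -7.55 over the 4 fits. The gut and Malpighian tubule list had one from -7.95 to -3.51 over 3 of them. Their added members could pass the filter through 1 library where they are high, so these fits are no repeated support. Apart from the length curve and the changed tests, the cause was not tested. The overlap of calls with the authors' deposited table was not run, as that table holds no p-values.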

Other observations

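All tests of explanations in this part were chosen only after the result was seen. The 3 tests set out before, on tissue carried over, strain background near wts and depth, were set on genes called by edgeR, which called 0 (914 at an unadjusted p under 0.05), and were not run on the 96 higher and 86 lower genes of DESeq2 or the 123 and 27 of limma-voom.

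Fat body genes were lower in wtsP2, and carried-over tissue, larval stage and genotype are candidate explanations. A single fat body profile present in a larger amount would move its genes alike only if the discs themselves made none of them. The 7 lower genes differed (Cochran Q = 55.3 on 6 degrees of freedom, and 126 on 11 over all 12 tested), Lsp1alpha and Fbp2 most. Without these 2, picked from their values so that this is no test, Q was 4.84 on 4. In wtsP2 Lsp1alpha had 3 and 12 counts and Fbp2 21 and 34, and the Lsp1 paralogs could share reads. Expression of these genes in the discs alone was not measured, so the test cannot decide. Carried-over fat body stays open as the whole or part of the cause. A lower share of disc tissue raising all other tissues alike was tested first by the haemocyte minus the fat body median. That left it open (2.98, permutation p = 0.13, two-sided). A Kruskal-Wallis test over 7 tissue lists, adopted because the first was undecided, gave H = 23.8 (permutation p = 0.00012). Without the fat body list it gave H = 12.2 (permutation p = 0.026). The permutations treat genes counted in the same 4 libraries as independent, so these p-values do not measure the spread between libraries. The salivary gland and gut lists (4 and 3 tested genes, medians -5.90 and -7.04) were left out as too small. The medians of the 7 lists ran from -3.70 for fat body to 0.90 for trachea, but the explanation stays open. A later stage of the wild-type larvae cannot be told apart, since ecdysone genes went both ways around a median of 0.243, and an effect of the genotype was not tested.

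Ribosomal protein and oxidative phosphorylation genes, both short, were lower in wtsP2, which may come from a trend with gene length. The length test was first camera after a length curve drawn without these genes, which gave adjusted p = 0.111 and 0.0160, and matched random sets were added after those values were seen. The curve left part of the trend in place (Spearman rho = 0.0751, against 0.176 before it). Of 10000 random sets matched on length and level, 53.2% had a median as low as the ribosomal proteins, in line with the trend, and 25.1% one as low as oxidative phosphorylation, where the trend stays open because camera still passed. The shallowest library alone is argued against, as both lists passed without it (adjusted p = 1.93e-05 and 0.00246), and without the first wild-type library both missed the threshold (0.989 and 0.136) while lying further below all genes (-1.03 and -1.34, against -0.46 and -0.69 with all libraries). An effect of the genotype stays open and was not tested.

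Genes at 0 where the other libraries predicted 20 to 40 counts numbered 1223 over the 4 libraries, which argues against depth alone. The prediction pools both groups, so genes that differ between the groups add to that number, by how much was not measured. A candidate explanation is that few RNA molecules were each read many times. From 20 to 40 up to 160 to 320 counts, a range chosen after the values were seen, the variance over its Poisson value rose by at most 1.41 times, where simulated counts with a fixed relative spread gave 6.8 times. Over other 8-fold ranges it rose by up to 7.15 times in wtsP2 and 3.30 times in wild type, so the explanation stays open. No biological explanation was tested.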
